A study of Homo sapiens with 3 samples.

How the data were processed

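RNA was measured in 3 libraries made from human embryonic stem cell lines. Bulk RNA-seq covered 1 library of neuro-cortical spheroids from the H7 line (day 92) and 1 library of oligo-cortical spheroids from the H9 line (day 94). Both were taken in week 14 from 4 pooled spheroids, and the oligo-cortical spheroids had received PDGF-AA and IGF-1 from day 50 to day 60 and the thyroid hormone T3 from day 62 to day 70. Single-cell RNA-seq covered 1 library of 10 pooled week 12 organoids of the H7 line. The labels give no growth protocol for these organoids, so they were assigned to neither spheroid group.

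The bulk values were deposited by the authors as FPKM (fragments scaled to transcript length and library size) after quantile normalization between the libraries. The sorted values of both libraries differed by at most 0.123 FPKM. TopHat2 2.0.6, Cufflinks 2.0.2 and the hg19 genome build are named in the submitters' processing notes, and the libraries were sequenced as paired reads of 50 bases per the labels. Read numbers were not given in the sources used here, so the depth of the bulk libraries was unknown and no counting interval could be given. Quantile normalization gives both libraries the same spread of values, so only the order of genes within each library carries information.

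The single-cell values were deposited by the authors as raw UMI counts (distinct captured transcripts) per gene and barcode, for barcodes that had passed a filter. Cell Ranger 2.1.0, STAR and hg19 are named in the submitters' processing notes. The library was made with a kit that reads transcripts at the 3' end, per the labels. The matrix held 3850 barcodes and 19781815 UMIs, with a median of 4158 UMIs (1835 to 49881) and 1870 genes per barcode.

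Of 24934 bulk genes in the table, 1292 entries on alternate or unplaced sequences, 28 entries whose name had turned into a date, 157 entries of XIST and Y-linked genes and 317 further entries of a repeated symbol were left out, which left 23140 genes. XIST and Y-linked genes were left out throughout. Gene names came from the files, and 3 list members were matched through an older symbol. Starts in the bulk table are counted from 0 and are given here counted from 1, on hg19. GENCODE release 29, which is on another build, served only for gene names and for transcript length and GC content, which 11687 of the 12229 measured genes had.

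The bulk comparison used log2((oligo-cortical FPKM + 1) / (neuro-cortical FPKM + 1)) for the 12229 genes with an FPKM of 1 or more in at least 1 library. All bulk folds and log2 differences are on this scale, which understates the change of low genes. With 1 library per group no test was possible and no p-value is given. A gene counted as higher or lower when at least 2-fold apart. For each of 36 gene lists with at least 5 measured members, the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart when its median lay outside the central 95% of these. That describes these 2 libraries, not the conditions.

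The genes named in the bulk comparison were set by rule. They were the 12 genes with the highest and the 12 with the lowest log2 difference among genes with an FPKM of 10 or more in at least 1 library, the 4 measured members of each list with the largest absolute difference, and 20 genes whatever their values. SST was named outside this rule, after its values were seen. In the single-cell library they were the same 20 genes, the genes of 5 lists kept out of the clustering, and the 5 genes that led each cluster.

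Cells with at least 500 genes and at most 10% mitochondrially encoded UMIs were kept in Scanpy 1.11.5. Scrublet marked 2 barcodes (0.0519%) as doublets, which were removed. Its sensitivity was not tested, and doublets may remain among the 3837 cells analysed. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used. The 5 lists kept out of the variable genes were thyroid hormone response, receptors and transporters for the added factors, cholesterol synthesis, IGF ligands and binding proteins, and node and paranode.

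Clusters were named from markers of 17 cell classes. A marker counted as raised in a cluster when 1.5-fold above all other cells and present in at least 5% of its cells. A cluster took the class with the largest share of its markers raised, given at least 3. Where the cluster's 10 leading genes by fold held at least 2 markers of another class, and more than of its own, it took that class if most of that class's markers, or as many as not, were raised and otherwise stayed unnamed. Glutamatergic, inhibitory and other neuron classes were merged into neuron-like cells.

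Class values are UPM, the UMIs of a gene out of every 1000000 UMIs summed over the cells of a class, with exact Poisson 95% intervals, and shares of cells have exact Clopper-Pearson 95% intervals. Where 0 cells had a UMI, the limit given is 3 cells of the total. These intervals cover counting error only, since cells of 1 library are not replicates. For shares of cells with a UMI, each cell was also thinned to 2000 UMIs, which left out 110 shallower cells of 3837. Free RNA was judged from a gene in classes that should lack it, which gives no level for rarer genes. Lists in radial glia-like against neuron-like cells were compared by log2((UPM + 10) ratio) over genes with at least 50 UMIs in both classes together. Where leaving out 1 cluster would move a printed class value of a gene in this comparison or of the 20 genes by over 1.5 times, the value by cluster is given for genes with at least 20 UMIs in the class, and this was chosen after seeing the data.

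The steps were tested on simulated data. With the neuro-cortical values of 11021 genes used for both bulk libraries and no noise between them, 100 of 100 genes raised 4-fold and 83 of 100 genes lowered 4-fold were recovered at 2-fold. This tested the calculation and gives no rate of false calls between real libraries. Of 300 random lists of 12 genes each, drawn from the 12229 bulk genes, 4% stood apart without a shift, 45.7% with a shift of 0.5, 90.3% with a shift of 1 and 100% with a shift of 2 on the log2 scale. For these lists the log2 differences had been shuffled among genes of similar expression, so members varied independently. Genes of a real list can vary together, so the 4% gives no rate of false calls for the real lists. In 5 draws of 2000 simulated cells, 100% of neuron, radial glia and cycling cells and 79.9% of choroid plexus cells were named correctly. These cells were drawn from the summed profiles of the classes that the same rule had named, without unnamed clusters or doublets. The rates therefore test the calculation and do not measure how often real cells were named correctly.

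The groups, gene lists, markers, named genes, thresholds and 18 alternatives were fixed before the data were examined. What follows was chosen after seeing the data. The naming rule was changed after clusters and simulated cells were seen. With neuron classes kept apart it left 2364 cells unnamed, with them merged 1497, and in the form used 1009. The earlier form named 38.7% of these simulated radial glia correctly. For cells simulated from the classes of the earlier form, both forms named 100% of radial glia correctly, and of choroid plexus cells the form used named 59.0% and the earlier form 18.1%. Also added afterwards were 4 alternatives, which removed genes listed at 0 together with loci under 300 bp, took the most different genes outside those, removed the transcript length and GC trend, and kept only cells with at least 0.2% mitochondrial UMIs. Locus length, transcript length and GC content were all looked at before that trend was chosen.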

Results

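The study grew cortical spheroids, balls of human brain tissue made from embryonic stem cells, and by its title aimed at oligodendrocytes, the cells that make myelin. Bulk RNA-seq covered 1 library of neuro-cortical spheroids (H7 line) and 1 library of oligo-cortical spheroids (H9 line), which alone had received PDGF-AA, IGF-1 and T3. Their values cover 24934 gene entries in FPKM, and their read depth is unknown. A single-cell library of week 12 organoids from the H7 line held 3850 barcodes and 19781815 UMIs, with a median of 4158 UMIs per barcode. Each group had 1 library, so no difference has a replicate check. The stem cell line changed together with the protocol, so no bulk difference could be assigned to the added factors.

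The bulk comparison asked how the RNA of oligo-cortical spheroids differs from that of neuro-cortical spheroids. Genes of connective tissue cells, glutamatergic neurons and dividing cells were higher in the oligo-cortical library, and genes of inhibitory neurons and synapses were lower. Of 12229 measured genes, 1734 were at least 2-fold higher, 1755 at least 2-fold lower and 8740 less than 2-fold apart. Of 36 gene lists, 23 had enough measured members to be described. The medians of 11 lay above and those of 3 lay below the central 95% of matched random lists.

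The difference was largest, among the 23 lists, for genes of mesenchymal cells and pericytes, which build connective tissue and vessel walls. Of 9 measured members 8 were at least 2-fold higher in the oligo-cortical library and 0 lower, with a median log2 difference of 4.80 (percentile 100 of random lists). COL3A1, a fibrillar collagen chain (chromosome 2, 189839099 to 189877472 on hg19), went from 1.92 FPKM in the neuro-cortical to 595 FPKM in the oligo-cortical library, a 204-fold difference with 1 FPKM added to both. COL1A1, a chain of type I collagen (chromosome 17, 48261457 to 48279000), stood at 3.44 and 199.6 FPKM. DCN and LUM, small proteoglycans that bind collagen, stood at 0.402 and 106 FPKM and at 0.258 and 58.0 FPKM. Among choroid plexus genes, TTR, which encodes a carrier of thyroid hormone made in that tissue (chromosome 18, 29171730 to 29178986), stood at 0.162 and 109.6 FPKM, and the water channel gene AQP1 at 0.235 and 19.8 FPKM. The choroid plexus list as a whole did not stand apart (6 measured, 3 higher and 1 lower, median 0.60, percentile 89.3). Its lower member was SLC4A10, a bicarbonate transporter also used by neurons (9.95 against 1.40 FPKM).

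Genes of oligodendrocytes were low in both libraries. Of the 12 members of the oligodendrocyte progenitor list only 2 reached 1 FPKM in a library. They were LUZP2, which was lower in the oligo-cortical library (4.39 against 0.505 FPKM), and SOX8, which was not 2-fold apart (3.41 against 4.78 FPKM). PDGFRA, the receptor for PDGF-AA, stood at 0.124 FPKM in the neuro-cortical and 0.510 FPKM in the oligo-cortical library, and OLIG2, a transcription factor of the lineage, at 0.158 and 0.887 FPKM. SOX10, which drives myelin genes, was listed at 0 and at 0.0208 FPKM.

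In the list of oligodendrocyte and myelin genes, 9 of 24 members were measured, 3 were at least 2-fold higher in the oligo-cortical library and 0 lower. Its median of 0.74 lay inside the central 95% of random lists (percentile 96.5). The higher members were GPR37 (0.818 against 4.79 FPKM), a receptor of maturing oligodendrocytes, MYRF (0.111 against 1.98 FPKM), a regulator of myelin genes, and PLLP (0.222 against 1.87 FPKM), a membrane protein of myelin. MBP, which compacts the myelin sheath, was not 2-fold apart (1.19 against 1.12 FPKM), and neither was UGT8, an enzyme of myelin lipid synthesis (0.340 against 1.25 FPKM). MOG, a protein of mature myelin, stood at 0.00551 FPKM and was listed at 0 in the oligo-cortical library, and MAG, a glycoprotein of the inner myelin wrap, was listed at 0 in both.

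Neuronal genes went both ways. Of 8 genes of glutamatergic neurons, the excitatory neurons of the cortex, 7 were higher in the oligo-cortical library and 0 lower (median 2.41, percentile 100). They included NEUROD6 (26.4 against 185 FPKM), a transcription factor of cortical projection neurons, TBR1 (6.13 against 41.4 FPKM), a regulator of deep-layer identity, EMX1 (0.695 against 14.0 FPKM) and the vesicular glutamate transporter SLC17A7 (2.95 against 24.7 FPKM). Of 11 genes of inhibitory neurons 7 were lower and 1 higher (median -1.54, percentile 0). GAD1, which makes the transmitter GABA, stood at 67.1 FPKM in the neuro-cortical and 9.81 FPKM in the oligo-cortical library, the non-coding RNA DLX6-AS1 at 76.3 and 7.48 FPKM, and ERBB4 at 8.13 and 0.369 FPKM. The member that was higher, named after its values were seen, was the neuropeptide SST (3.31 against 10.2 FPKM).

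Genes shared by all neurons were lower in the oligo-cortical library (14 measured, 4 lower, 0 higher, median -0.66, percentile 0.44). DCX, a microtubule protein of young neurons, stood at 92.6 and 26.4 FPKM, STMN2 at 328 and 138 FPKM, and the neurofilament genes NEFM and NEFL at 46.3 and 15.3 and at 88.3 and 36.7 FPKM. Synaptic genes were lower too (14 measured, 5 lower, 0 higher, median -0.58, percentile 1.79), among them the glutamate receptor subunits GRIA2 (138 against 14.8 FPKM) and GRIA1 (108 against 14.6 FPKM). With genes under 5 FPKM left out, 7 synaptic genes remained and their median of -0.49 no longer stood apart (percentile 8.09). Deep-layer genes had members on both sides (3 higher and 2 lower of 8, median 0.45, percentile 82.8), with CRYM, a thyroid hormone-binding protein, higher (0.589 against 10.5 FPKM) and FOXP2 lower (27.6 against 3.59 FPKM). BCL11B, another deep-layer regulator, stood at 2.83 and 1.99 FPKM. Of 5 upper-layer genes only RORB was 2-fold higher (1.26 against 3.58 FPKM), and the list did not stand apart (median -0.30, percentile 23.1). Genes of the node of Ranvier and its flanks did not stand apart either (11 measured, 4 lower, 0 higher, median -0.23, percentile 15.7). Among them the sodium channel SCN1A (3.66 against 0.311 FPKM) and its anchor ANK3 (16.8 against 3.06 FPKM) were lower. With a trend over transcript length and GC content removed, the median of this list turned to 0.47 (2 higher, 2 lower, percentile 90.7) and SCN1A was less than 2-fold apart (-0.70).

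Progenitor genes were higher in the oligo-cortical library where they mark division or the step to neurons. Of 8 intermediate progenitor genes 5 were higher and 0 lower (median 1.66, percentile 99.99), among them the transcription factors NEUROG2 (2.25 against 18.2 FPKM) and EOMES (1.25 against 7.23 FPKM). Of 15 proliferation genes 10 were higher and 0 lower (median 1.45, percentile 100), with UBE2C, a ubiquitin-conjugating enzyme of mitosis, at 16.9 and 88.3 FPKM and AURKB, a mitotic kinase, at 2.59 and 16.9 FPKM. MKI67, the usual marker of division, was not 2-fold apart (1.98 against 1.44 FPKM). Astrocyte genes were higher (10 measured, 5 higher, 0 lower, median 1.04, percentile 99.9), with the gap junction gene GJA1 at 0.154 and 4.31 FPKM, S100B at 0.368 and 5.12 FPKM and GFAP at 0.178 and 1.76 FPKM. AQP4, an astrocyte water channel, stood at 0.354 and 0.546 FPKM, and the glutamate transporter SLC1A3 at 39.6 and 21.7 FPKM. Radial glia genes, of the stem cells of the cortex, did not stand apart (12 measured, 2 higher, 1 lower, median -0.14, percentile 17.1), and neither did those of outer radial glia (7 measured, 1 higher, 0 lower, median 0.07, percentile 45.5).

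Regional genes differed in both directions. The forebrain identity list had 3 higher and 2 lower members of 8 (median 0.75, percentile 97.4, inside the central 95%). The cortical regulator LHX2 was higher in the oligo-cortical library (13.8 against 49.2 FPKM). SIX3, which marks the front of the brain, was lower (9.36 against 0.978 FPKM). Of 8 genes of the ventral telencephalon 4 were measured, of which DLX1 (41.5 against 17.1 FPKM) and GSX2 (6.25 against 2.60 FPKM) were lower. Of 13 hindbrain and spinal cord genes 2 were measured. These were HOXB2 and GBX2, which were listed at 0 in the neuro-cortical library and stood at 4.94 and 2.17 FPKM in the oligo-cortical library.

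Several response lists were higher in the oligo-cortical library. Of 11 immediate early and heat shock genes 8 were higher and 0 lower (median 1.31, percentile 100), including the activity-driven genes EGR1 (2.41 against 21.4 FPKM) and IER2 (9.95 against 66.4 FPKM). Genes of the unfolded protein response, which deals with misfolded secretory proteins, were higher (16 measured, 7 higher, 0 lower, median 0.73, percentile 99.5), with the chaperone HSPA5 at 25.6 and 71.0 FPKM. Hypoxia and glycolysis genes followed (18 measured, 6 higher, 0 lower, median 0.65, percentile 99.2), with the glucose transporter SLC2A1 at 15.2 and 68.8 FPKM and CA9 at 0.776 and 7.63 FPKM. Genes of cholesterol synthesis, a lipid that myelin needs in quantity, were higher as a list (23 measured, 5 higher, 0 lower, median 0.60, percentile 98.6), with DHCR7, the enzyme of the last step, at 10.2 and 32.3 FPKM and PMVK at 8.72 and 27.7 FPKM.

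Genes tied to the added factors gave a mixed picture. IGF ligands and binding proteins were higher (8 measured, 5 higher, 1 lower, median 1.75, percentile 100), with the binding protein IGFBP7 at 3.53 and 50.5 FPKM and IGF2, a fetal growth factor, at 0.0160 and 4.59 FPKM. Receptors and transporters for PDGF, IGF and thyroid hormone did not stand apart (7 measured, 1 lower, 0 higher, median -0.41, percentile 13.7). The lower member was RXRG, a partner of the thyroid hormone receptor (8.65 against 2.19 FPKM). Of 9 thyroid hormone response genes 4 were measured. NRGN (8.80 against 0.161 FPKM) and CAMK4 (10.2 against 3.55 FPKM), calcium-calmodulin genes of neurons, were lower in the oligo-cortical library, and DIO3, the enzyme that inactivates thyroid hormone, was higher (0.149 against 1.43 FPKM). KLF9, a direct target of the hormone, stood at 0.00901 and 0.0396 FPKM. Genes known to vary between human lines were also higher (5 measured, 4 higher, 0 lower, median 1.90, percentile 100), with the imprinted genes DLK1 at 20.3 and 566 FPKM and H19 at 0.0243 and 14.8 FPKM.

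Of the 36 lists, 13 had under 5 measured members and were not placed among random lists. A gene was measured if it reached 1 FPKM in either library, so these small counts show only in which library the members passed. Of 8 endothelial genes 3 passed in the oligo-cortical and 0 in the neuro-cortical library, with CLDN5, a tight junction protein of vessels, at 0.0478 and 9.08 FPKM in the neuro-cortical and the oligo-cortical library. Of 8 pluripotency genes it was 3 and 0, with DPPA4 at 0.0621 and 2.08 FPKM. Of 10 neural crest and Schwann cell genes 3 passed in the oligo-cortical and 1 in the neuro-cortical library, with PMP22 at 1.57 and 10.1 FPKM, and of 10 muscle genes also 3 and 1, with TNNT1 at 1.14 and 25.1 FPKM. Of 9 microglia genes 1 passed in the oligo-cortical library and 0 in the other, AIF1 (0.381 and 4.26 FPKM). Of 9 ciliated and ependymal genes it was 4 and 0, with TPPP3 at 0.930 and 8.14 FPKM, and of 11 retina and pigment genes 4 and 2. Of the genes that passed, 2 of muscle, 1 of endothelium, 1 of pluripotency and 1 of ciliated cells were listed at 0 in the neuro-cortical library. The lists of mitochondrially encoded and of red blood cell genes had 0 measured members. A gene missing from the bulk values counts the same way as one under 1 FPKM, so this does not show low expression.

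**Figure D1:**
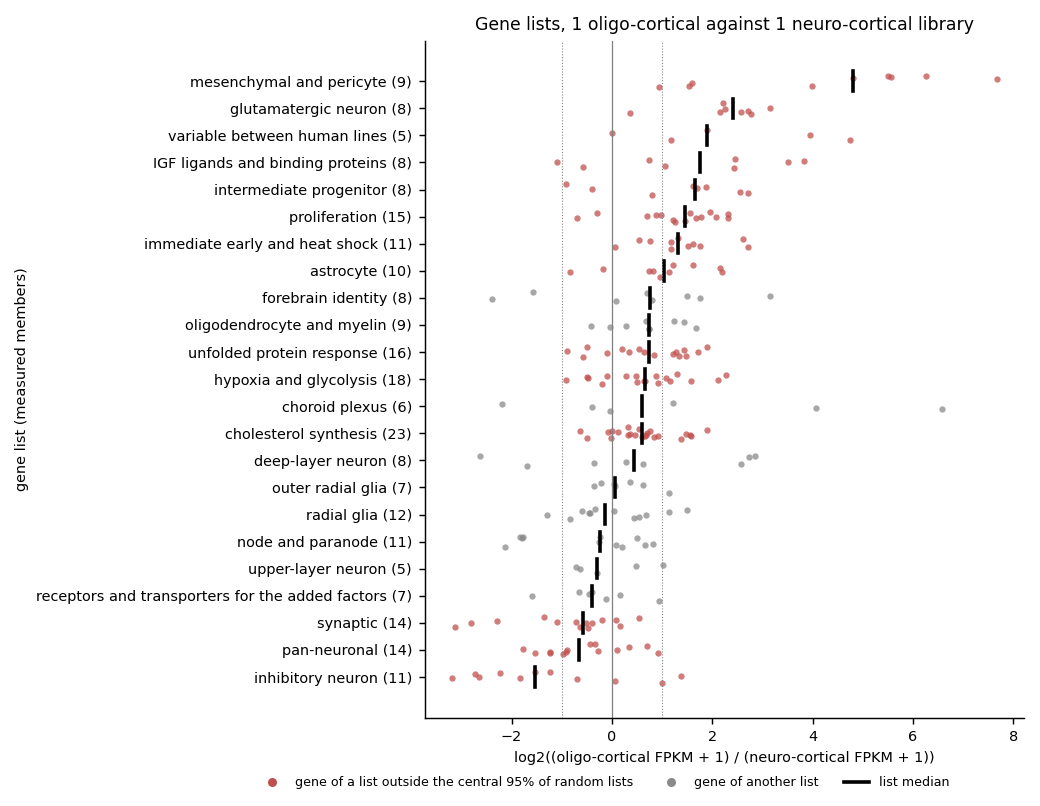
Each point is 1 measured gene of a list, placed by its log2 difference between the oligo-cortical and the neuro-cortical library, and the black bar is the list's median. The medians run from 4.80 for mesenchymal and pericyte genes to -1.54 for inhibitory neuron genes, and dotted lines mark 2-fold.

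The largest single differences lay mostly in very short RNAs and in genes listed at 0. Of the 12 highest genes 11 had a locus under 300 bp and 11 were listed at 0 in the neuro-cortical library, and COL3A1 was the exception to both. Of the 12 lowest genes 10 had a locus under 300 bp and 11 were listed at 0 in the oligo-cortical library. Those with a longer locus were NNAT, an imprinted neuronal gene (chromosome 20, 36149607 to 36152090), at 1114 and 0.404 FPKM, and ACTB, the cytoskeletal actin of every cell (872 FPKM and listed at 0). An exact 0 in these values can therefore be a failed estimate, and 105 genes were listed at 0 in the oligo-cortical library with 10 FPKM or more in the other. Among genes above 0 with a locus of at least 300 bp, a choice made after the values were seen, COL3A1, the epithelial keratin KRT19 (0.380 against 148 FPKM), TTR and the interferon-induced IFITM3 (0.754 against 163 FPKM) were the 4 highest. Next to NNAT, the splicing factor LUC7L3 (444 against 16.2 FPKM) was among the lowest of these.

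The split of higher and lower genes depended on the zero point of the scale. Centred on the median of 0.20 over the 3009 genes with 10 FPKM or more in both libraries, it was 1215 higher and 2319 lower. Differences also followed transcript length and GC content (Spearman across genes -0.296 and 0.235, genes not being replicates). With that trend removed, 10 of the 11 lists above and 3 of the 3 below still stood apart, and the list of genes variable between lines kept only 4 genes with a known length and was not placed. CAMK4 (-0.62), DIO3 (0.66) and SST (0.76) were then less than 2-fold apart. Values of the libraries correlated across genes with a Spearman coefficient of 0.713.

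The single-cell library was used to ask which cell types an H7 organoid holds and where genes of the oligodendrocyte lineage are expressed. The 3837 cells analysed fell into 17 clusters, of which 13 could be named. Neuron-like cells made up 49.0% (1882 cells, 95% interval 47.5 to 50.6%), radial glia-like cells 20.3% (779 cells, 19.04 to 21.6%), choroid plexus-like cells 3.08% (118 cells, 2.55 to 3.67%) and cycling-like cells 1.28% (49 cells, 0.946 to 1.68%). No cluster was oligodendrocyte-like or oligodendrocyte progenitor-like, which leaves open single such cells within other clusters. The remaining 26.3% (1009 cells, 24.9 to 27.7%) lay in 4 clusters that stayed unnamed. Under other settings the choroid plexus-like share ranged from 1.43 to 5.79% and the cycling-like share reached 5.50%.

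Neuron-like clusters were defined by genes of different neuron types. Leading genes were LHX9 and the glutamate transporter SLC17A6 in cluster 11, GATA3, TAL2 and GATA2, regulators of midbrain inhibitory neurons, in cluster 12, SST in cluster 13, NEUROD1 and NEUROD6 in cluster 7, and the choline transporter SLC5A7 of cholinergic neurons in cluster 16. Cluster 1, also neuron-like, was led by the pigment cell gene PMEL and the cell death gene BBC3. Radial glia-like cells were led by SLC1A3 and CYP26B1 in cluster 6 and by RSPO genes, which enhance WNT signals, in cluster 14. The choroid plexus-like cluster was led by TTR, with IFITM3, IGFBP7 and the collagen gene COL1A2 beside it, and also had 6 markers of ciliated cells raised. Unnamed clusters were led by metallothionein genes such as MT1X and MT2A in cluster 10 and by the heat shock gene HSPA6 and the lysosomal glycoprotein gene GPNMB in cluster 3. Median depth differed between classes, from 3537.5 UMIs in neuron-like to 6216 in radial glia-like and 8126.5 in choroid plexus-like cells.

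**Figure D2:**
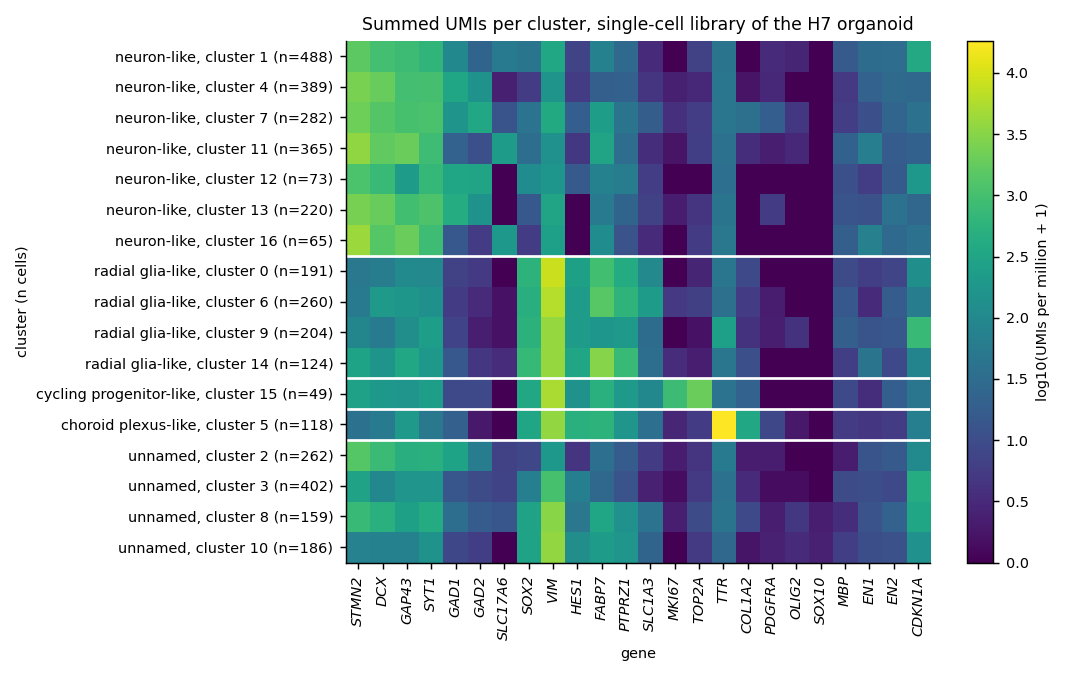
Colour gives log10 of UPM plus 1 for marker genes (columns) in each of the 17 clusters of the single-cell library (rows, with the number of cells). DCX and STMN2 are high in neuron-like clusters, VIM and PTPRZ1 in radial glia-like clusters and TTR in the choroid plexus-like cluster.

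Among genes of oligodendrocytes, MBP had a UMI in 168 cells (4.38%, and 1.69% with each cell thinned to 2000 UMIs). It stood at 12.6 UPM (UMIs out of every 1000000 of the class, 9.77 to 16.1) in radial glia-like and 12.2 UPM (9.75 to 14.97) in neuron-like cells, so no order between these classes could be read. MBP was not among the genes used in the clustering. Free RNA was read from TTR, which neurons should lack. TTR stood at 43.2 UPM in neuron-like cells with a UMI in 15.2% of them (8.78% thinned), against 18308 UPM in choroid plexus-like cells. That level goes with how abundant TTR is, so it gives no free RNA level for rarer genes such as MBP.

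Genes that mark the oligodendrocyte lineage itself were rare. SOX10 had UMIs in 3 cells, all in unnamed clusters, and OLIG2 in 23 cells (0.599%, and 0.241% thinned), of which 10 were neuron-like and 5 radial glia-like, all 5 in cluster 9. PDGFRA had UMIs in 42 cells (1.09%, and 0.644% thinned), at 4.28 UPM (2.91 to 6.08) in neuron-like, 0.766 UPM (0.209 to 1.96) in radial glia-like and 7.37 UPM (3.18 to 14.5) in choroid plexus-like cells. Of its 31 UMIs in neuron-like cells 18 lay in cluster 7, at 17.8 UPM (10.6 to 28.1), where the collagen gene COL1A2 stood at 36.6 UPM. The other neuron-like clusters together stood at 2.09 UPM (1.11 to 3.57) of PDGFRA, an interval that overlapped that of radial glia-like cells. MOG had UMIs in 5 cells and MYRF in 6, and MAG had 0 in 3837 cells, which allows up to 0.0782% of cells with a UMI (3 cells of the total). The astrocyte genes GFAP and AQP4 were rare as well, GFAP with UMIs in 12 cells, of which 9 were radial glia-like, and AQP4 in 11, of which 8 were choroid plexus-like. SLC1A3, a member of both the astrocyte and the radial glia list, was not rare, with UMIs in 457 cells (11.9%, and 5.58% thinned). Whether cells with UMIs of SOX10, OLIG2, MOG or MYRF expressed these genes or took up free RNA was not tested. The level of TTR cannot decide it, since free RNA depends on each gene's own abundance.

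The clustering used several of the other named genes, so their levels describe the classes. DCX and STMN2 reached 1470 and 2505 UPM in neuron-like cells, SLC1A3 stood at 108 UPM in radial glia-like cells (220 UPM in cluster 6 and 54.9 UPM in the others) and 5.11 UPM in neuron-like cells (16.8 UPM in cluster 7 and 3.21 UPM in the others), and MKI67 reached 824 UPM in cycling-like cells. GAD1 stood at 179 UPM in neuron-like cells, with a UMI in 34.2% of them (25.5% thinned). Of cortical genes, TBR1 had 16 UMIs in 12 cells and BCL11B had UMIs in 282 cells. KLF9, the thyroid hormone target, stood at 3.83 UPM (2.34 to 5.91) in radial glia-like and 0.967 UPM (0.389 to 1.99) in neuron-like cells. Outside cluster 6 the radial glia-like value was 2.53 UPM (1.16 to 4.81), which overlapped that of neuron-like cells.

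Of the lists kept out of the clustering, genes of the node of Ranvier and its flanks were lower in radial glia-like than in neuron-like cells (12 measured, 6 at least 2-fold lower, 0 higher, median -0.83, percentile 0). SCN2A, a sodium channel of axons, stood at 6.32 UPM in radial glia-like and 94.7 UPM in neuron-like cells, its anchor ANK3 at 38.7 and 207 UPM, and the adhesion molecule CNTN2 at 1.91 and 48.7 UPM. Cluster 7 held 198 of the 353 neuron-like UMIs of CNTN2, and the other neuron-like clusters stood at 24.9 UPM. Receptors and transporters for the added factors did not stand apart (10 measured, median 0.19, percentile 94.4). THRA, the main thyroid hormone receptor of the brain, stood at 66.3 and 116 UPM, the insulin receptor INSR at 26.4 and 54.5 UPM, and PDGFRB at 11.3 UPM with 59 UMIs (28.2 UPM in cluster 0 and 6.41 UPM in the others) against 0 UMIs. IGF genes did not stand apart (8 measured, 2 higher, 0 lower, median -0.02, percentile 63.7), although the binding proteins IGFBP2 (2233 against 828 UPM) and IGFBP5 (110.1 against 34.7 UPM) were higher in radial glia-like cells. Of the 251 neuron-like UMIs of IGFBP5 148 lay in cluster 7, and the other neuron-like clusters stood at 16.5 UPM. Cholesterol synthesis genes did not differ by 2-fold in any of 22 measured members (median -0.12, percentile 34.9), and only 3 thyroid hormone response genes were measured.

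Mitochondrially encoded transcripts split the cells into groups with few cells between them. Of the 3837 cells 1252 (32.6%, 31.1 to 34.1%) had under 0.2% of their UMIs from mitochondrial genes, 289 of them had none, and 333 cells lay between 0.1 and 0.5%. Clusters 1, 3 and 9 consisted mostly of such cells (90.2%, 88.8% and 96.1%). Their median of 4183.5 UMIs was close to that of the other cells (4152).

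**Figure D3:**
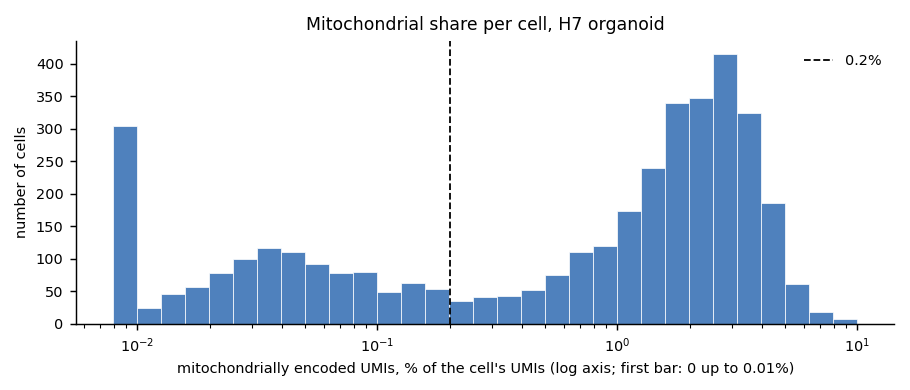
Bars give the number of cells by the percent of their UMIs that came from mitochondrially encoded genes, on a log axis, with a dashed line at 0.2%. To the left of the line lie 1252 of 3837 cells, and 333 cells lie between 0.1 and 0.5%.

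Placing the bulk differences on the cell classes asked in which cells of the H7 organoid those genes are expressed most. Only the 10760 measured bulk genes with at least 20 UMIs in the single-cell library could be placed, and the genes most higher or lower were taken among these. Of the 100 genes most higher in the oligo-cortical library, 64 had their highest level in choroid plexus-like cells, against 7 to 20 in the central 95% of matched random lists, among them COL3A1, TTR, DCN and LUM. That class was mixed. COL3A1 and LUM were concentrated in its 43 cells with a COL1A2 UMI, whereas TTR was higher in the other 75. Only 9 of the 100 higher genes peaked in neuron-like cells (random 22 to 40). Of the 100 genes most lower, 56 peaked in neuron-like cells (random 21 to 39), among them NNAT and LUC7L3, and 4 in choroid plexus-like cells (random 7 to 21). Cycling-like cells held 8 of the higher genes (random 13 to 29) and 22 of the lower genes (random 12 to 27). Across 11221 genes the summed single-cell library correlated with the neuro-cortical library at a Spearman coefficient of 0.624 and with the oligo-cortical library at 0.552. The single-cell library shares the H7 line with the neuro-cortical library alone and differs from both in age and method, so the link describes genes and not the makeup of the spheroids.

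**Figure D4:**
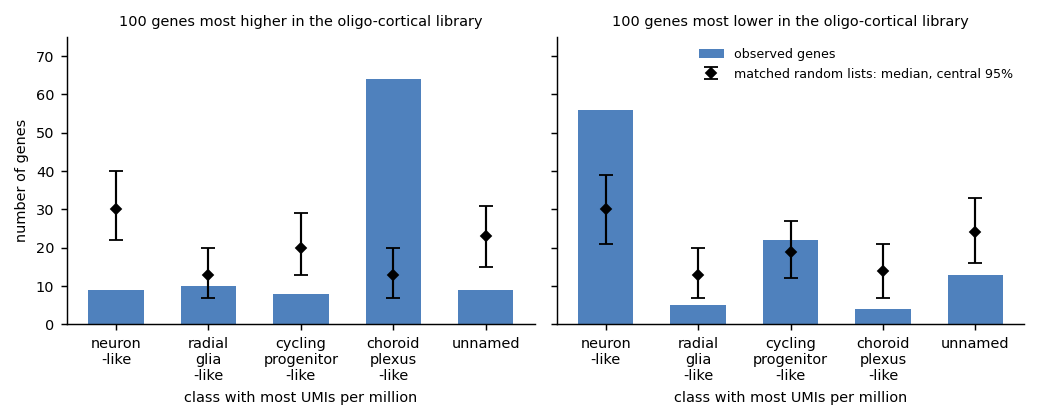
Bars give how many of the 100 genes most higher (left) or most lower (right) in the oligo-cortical library, among genes with at least 20 UMIs, have their highest UPM in each class of the single-cell library. Diamonds and whiskers give the median and the central 95% of matched random lists, and choroid plexus-like cells hold 64 of the higher genes.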

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

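Of the alternatives, 4 were added after seeing the data, namely the removal of genes listed at 0 and loci under 300 bp, the most different genes outside those, the removal of the transcript length and GC trend, and keeping only cells with at least 0.2% mitochondrial UMIs. No paired analysis was possible because each group has only replicate 1. No list median outside the central 95% and no value of a listed gene past 2-fold changed sign. Values short of that did. With the length and GC trend removed, 25 of 282 listed or named genes with a known length changed sign, among them MKI67 (-0.29 to 0.48), MBP (-0.04 to 0.51), BCL11B (-0.36 to 0.08) and IGF1R (-0.46 to 0.16), as did the medians of the node and paranode list (-0.23 to 0.47) and the radial glia list (-0.14 to 0.04). The median of the node and paranode list was also positive among genes at 5 FPKM or more (0.08), and that of outer radial glia negative after centring (-0.13). Between radial glia-like and neuron-like cells, the median of IGF genes was positive under 8 of the 8 alternatives that gave one, and among cells with at least 0.2% mitochondrial UMIs those of receptors and transporters (-0.15) and of cholesterol synthesis (0.07) changed sign. Of 118 named bulk genes at least 2-fold apart, 9 fell under 2-fold with the length and GC trend removed. SST, which was named outside the rule, did so too. Where values moved the cause was not tested unless stated. Of 177 list medians under alternatives 172 kept their place inside or outside the central 95% of random lists, and 81 of 85 values of single named bulk genes kept their side of 2-fold. With a pseudocount of 5, which shrinks low genes, 559 genes were higher and 773 lower, and the oligodendrocyte and myelin list, at a median of 0.37, now stood apart (percentile 99.4). MYRF (0.45) and GFAP (0.38) were then under 2-fold. A 3-fold threshold, stricter by construction, left 570 higher and 805 lower genes. With a pseudocount of 0.1 the medians of choroid plexus genes (1.86) and forebrain genes (1.02) stood apart, as did forebrain genes with the length and GC trend removed. SLC1A3 passed 2-fold after centring (-1.03). Class shares depended on the clustering, and 31 of 63 values under alternatives lay outside the counting interval of the share reported. Neuron-like cells made up 53.6% with no filter on cells, 52.3% with at least 1000 genes per cell, 44.7% with doublets kept, 55.8% at resolution 0.5, 45.3% with 4000 variable genes and 56.9% with 15 principal components. Radial glia-like cells made up 14.4% with no filter, 16.2% with at least 1000 genes, 14.9% with doublets kept, 18.8% at resolution 0.5, 14.3% at resolution 2, 22.1% with 4000 variable genes and 22.5% among cells with at least 0.2% mitochondrial UMIs. Cycling-like cells made up 1.72% with doublets kept, 5.50% at resolution 0.5 and 2.51% among cells with at least 0.2% mitochondrial UMIs. Choroid plexus-like cells made up 1.43% with at least 1000 genes, 2.40% with doublets kept, 5.79% at resolution 0.5, 2.45% at resolution 2, 1.90% with 15 principal components and 4.22% among cells with at least 0.2% mitochondrial UMIs. The shares of oligodendrocyte-like and oligodendrocyte progenitor-like cells were 0 under all of these settings. With 50 genes in place of 100, 2% of the higher genes peaked in radial glia-like cells and now fell below the random range, while 6% of the lower genes in radial glia-like cells, 8% in choroid plexus-like cells and 16% in unnamed clusters now lay within it. Choroid plexus-like cells held 82% of the higher genes with 50 genes and 59.5% with 200, above the random range in both. Depth limits what can be said of the oligodendrocyte lineage, since a gene with UMIs in 3 cells, such as SOX10, can be neither placed nor excluded in a class.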

Other observations

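Tests reported here were chosen after the result was seen, except that of further p53 targets, and so were the gene groups described. The single-cell library held transcripts of some genes that pattern the border of midbrain and hindbrain. CNPY1, an FGF signalling gene of that region, had 574 UMIs, the transcription factors EN1 and EN2 had 359 and 334, GBX2 had 97, PAX2 had 80, PAX8 had 32, PAX5 had 24, and the signals FGF8 and WNT1 had 5 and 0. EN1 was seen in 273 of 3837 cells (7.11%, and 3.54% with each cell thinned to 2000 UMIs). Genes of the telencephalon had few UMIs, with 0 for EMX1 and DLX6-AS1, 1 for DLX5, 2 for DLX1, DLX6 and LHX6, 9 for GSX2, 10 for SLC17A7, 12 for DLX2, 16 for TBR1 and 47 for FEZF2. In the H7 bulk library DLX5 stood at 75.1 FPKM and DLX6-AS1 at 76.3 FPKM.

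Within the choroid plexus-like cluster, collagen genes were concentrated in part of the cells. In its 43 cells with a UMI of COL1A2 (median 8471 UMIs), COL3A1 stood at 260 UPM (212 to 316), COL1A1 at 263 UPM (214 to 319) and LUM at 161 UPM (123 to 206). In the 75 cells without one (median 7653 UMIs) these stood at 5.77 UPM (1.57 to 14.8), 23.1 UPM (13.2 to 37.5) and 12.99 UPM (5.94 to 24.7). Few cells carried these values, with UMIs of COL3A1 in 17 and 4 cells, of COL1A1 in 10 and 9 and of LUM in 11 and 5. The intervals count UMIs and do not cover the spread between cells. The choroid plexus epithelium genes TTR and HTR2C went the other way, with 10173 against 22910 UPM and 135 against 218 UPM. TTR had UMIs in 24 and 55 cells and HTR2C in 10 and 24. DCN was not apart, at 30.6 and 21.6 UPM, with UMIs in 3 and 9 cells.

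Mesenchymal genes were higher in the oligo-cortical bulk library. As a hypothesis, that library may have held cells with the transcript mix of the choroid plexus-like cluster, whose other leading genes were also higher there (41 of 50 measured, 28 at least 2-fold higher and 1 lower, median 1.69, percentile 100). Against this as the whole source, the mix would bring a median of 144 times the TTR rise observed, from 10.7 times for PDGFRB to 1017 times for COL3A1. A trend with transcript length and GC content does not account for it either, since the median was 4.82 with the trend removed. Stromal cells in another proportion, the protocol and the cell line stay open, and with 1 line per protocol the cell line and the protocol cannot be told apart.

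Few telencephalic transcripts in the single-cell library, against the H7 bulk library, could reflect its depth or single genes lost in 3' counting. Against depth, genes at the bulk level of DLX5, which had 1 UMI, had a median of 4822 UMIs, and the 10th percentile of UMIs among genes at the bulk level of each listed gene had a median of 233 over the list. FEZF2, with 47 UMIs, was at that percentile for its level. Loss of single genes stays open, since these genes were picked after such low values were seen. Of the 5 other measured members of the forebrain lists fixed earlier, 40%, SIX3 and LHX2, lay below the 10th percentile of genes at their level. Another growth protocol or another sample than the bulk spheroids also stays open, since the labels give 0 growth protocols for this library, and these cannot be told apart.

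Cells poor in mitochondrial transcripts expressed CDKN1A, which halts the cell cycle, at 489 UPM (473 to 507) against 70.2 UPM (65.7 to 74.9) in other cells, GDF15 at 315 against 20.1 UPM and MDM2 at 148 against 46.5 UPM. Droplets with little RNA are argued against by a ratio of median UMIs of 1.01, and nuclei or cells that lost their cytoplasm by ribosomal protein transcripts at 0.864 times the share in other cells (17.9 against 20.8%), although MALAT1, a nuclear RNA, was higher (9.29 against 6.71%). A p53 response may be part of the state of these cells. Of 13 further p53 targets picked without their values, 13 were higher, 3 of them at least 2-fold (median 0.82, percentile 100), and within radial glia-like cells, where 196 of the 211 such cells formed cluster 9, the percentile of 12 targets was also 100. No biological group of the design was tested, and damage during dissociation stays open.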
